A study of Homo sapiens with 4 samples.

How the data were processed

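The series measured RNA bound by Argonaute 2 (Ago2), the protein that carries microRNAs (miRNAs) to their targets, by crosslinking, immunoprecipitation and sequencing (CLIP-seq) in HEK293T, a cultured human embryonic kidney line. Per the labels' protocols, cells received cycloheximide, an inhibitor of translation elongation, at 100 µg/mL for 10 min at 37 °C and were irradiated with ultraviolet light at 120 mJ/cm2. Lysates were then spun at 36000 rpm for 2.5 h through a sucrose gradient of 10 to 50%. Ago2 complexes were precipitated from the light ribonucleoprotein (LRNP) fraction or the polysome (PS) fraction, digested with micrococcal nuclease and dephosphorylated. Linkers were ligated to the RNA ends, and the cDNA was amplified for 20 PCR cycles. Groups and replicate numbers were taken from the labels, which give 4 libraries, 2 for each fraction. In both groups the labels give an Abnova antibody for replicate 1 and an Abcam antibody for replicate 2.

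The authors deposited 1 table of raw read counts per feature, with a column for each library. Per the file headers, the counts came from sorted alignments, and a column of feature lengths in nucleotides accompanied them. The submitters' processing notes name STAR 2.5.2a, FastQC and the human genome build hg38. The counting tool, the treatment of reads that map to several places and the reference behind the alignments are not given in the sources used here. The table had 2922 features, of which 2654 were mature miRNAs of 16 to 28 nucleotides and 268 were tRNA genes of 70 to 108 nucleotides. The tRNA genes fell into 49 isoacceptor families (same amino acid and anticodon, with initiator and elongator tRNA-Met apart). Near-identical tRNA genes, and miRNAs made from several loci, share reads, so single tRNA genes are uncertain and a sum over a family can hold a read more than once if the authors' counting allowed it. A total here is the sum over these features and not all sequenced reads. Messenger, ribosomal and other RNAs were not analysed here.

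Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and PS was compared with LRNP by glmQLFit (robust) and glmQLFTest without a block. Log2 fold changes are PS minus LRNP, standard errors (SE) were derived from the fold change and its F statistic, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are TMM-scaled CPM. Counts were also summed over each isoacceptor family and fitted again with the other features kept; this fit has its own scaling, under which the 1310 tested miRNAs lay lower by a median log2 change of -0.89. Shares were taken of each library's total. They were compared by a two-sided exact permutation test, whose smallest p with 2 against 2 libraries is 0.333, and a Wilson interval of 95% was computed for each library. Intervals and floors cover counting error only, because no molecular identifiers are described. The labels do not say that replicates came from separate cultures, so p-values of comparisons between libraries measure only the spread between these libraries.

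Of 32 lists fixed before the data were examined, 11 had features in the table. Lists with 3 or more tested members were compared with the other features by limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with the estimated correlation and with fry. Lists matched by name pattern also took in miR-122b, miR-371b and miR-451b. Features were named by a rule fixed at the same time, which took all tRNA-Met genes, the 12 largest fitted changes in each direction that passed the threshold with the groups apart, the 10 most abundant features and the 3 most abundant tested members of each list. Hairpin positions come from GENCODE release 29 (2574 of 2654 miRNAs matched by name) and tRNA positions from RefSeq on GRCh38.p14 (249 of 268 matched), both on the GRCh38 assembly that hg38 denotes.

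Replicates differed by more than sampling noise. Chi-square per degree of freedom was 7.57 over 734 features in LRNP and 8.77 over 1844 in PS, so all 4 libraries were kept as separate samples. The antibody ties the replicate numbers of both groups together, so the pairing was checked. The deviations of same-numbered libraries from their group means had a Pearson correlation of -0.090 and a Spearman correlation of -0.048 across 462 features, which are not independent replicates. On simulated counts for PS against LRNP, in 1304 features that passed the filter, 60 of 100 features changed 2-fold and 83 of 100 changed 4-fold were recovered, and 13 of 156 calls (8.33%) were false. The median estimates were 0.99 and 2.07 on the log2 scale. That share of false calls exceeds the 5% the threshold aims at. The simulation had changes balanced in direction, left most features unchanged and gave both fractions the same composition otherwise. In the data 1505 of 1578 tested features differed and the composition shifted strongly, so these rates may not hold for the comparison itself.

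Alternatives were RLE size factors, library totals only, upper-quartile scaling, no filter beyond 1 count, at least 50 counts in 2 libraries, DESeq2 1.42.0, limma voom, the replicate as a block, and each library left out in turn. For class shares, the most abundant feature of each library was also removed. Chosen after the data were seen were a fit within each class, the most counted gene of a family standing for that family, tRNA shares with each family counted once, and the miRNA lists' shares of miRNA reads only. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.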

Results

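RNA precipitated with Ago2 was counted in the light ribonucleoprotein (LRNP) and polysome (PS) fractions of HEK293T cells, with 2 libraries for each fraction. The labels give no library of total RNA or of a control precipitation. Differences in Ago2 binding therefore cannot be told apart from differences in the amount of an RNA in each fraction or from unspecific precipitation. Counts per gene also do not tell whole tRNAs from fragments. Library totals were 5267120 and 6653799 reads in LRNP replicates 1 and 2, and 5091788 and 7258579 reads in PS replicates 1 and 2. The most abundant feature was miR-19b-3p in both LRNP libraries (8.04% and 7.77% of reads) and miR-18a-5p in both PS libraries (12.3% in each). In PS replicates 1 and 2, 35 and 11 features had 0 reads, against 1680 and 1499 in LRNP replicates 1 and 2. A count of 0 allows up to 3 reads, which is 0.570 and 0.451 CPM in LRNP replicates 1 and 2.

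The series title concerns Argonaute binding to the initiator tRNA-Met, the tRNA that starts protein synthesis. The first comparison asked how the classes of RNA precipitated with Ago2 differed between the fractions. tRNA reads made up 45.4% ± 0.490 (SD, n = 2) of the counted reads in LRNP and 2.50% ± 0.0328 (SD, n = 2) in PS, an 18.2-fold higher share in LRNP. miRNAs made up 54.6% ± 0.490 (SD, n = 2) in LRNP and 97.5% ± 0.0328 (SD, n = 2) in PS. Initiator tRNA-Met held 2.78% ± 0.0242 (SD, n = 2) of LRNP reads and 0.0414% ± 0.000958 (SD, n = 2) of PS reads, a 67.2-fold difference. The elongator tRNA-Met genes, which supply methionine within proteins, held 0.280% in LRNP and 0.00907% in PS, a 30.9-fold difference.

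Among the amino acids, tRNA-Lys held the most reads in LRNP, at 18.4% against 0.133% in PS, a 138-fold difference. tRNA-Gly was 35.8-fold, tRNA-Asp 11.1-fold and tRNA-Glu 7.72-fold higher in LRNP by share. For a single library, the Wilson 95% interval of the initiator share ran from 2.79% to 2.81% in LRNP replicate 1 and from 0.0404% to 0.0439% in PS replicate 1. In each of these tRNA classes both LRNP libraries lay above both PS libraries, with either antibody. The exact permutation test gave p = 0.333 for each, the smallest value 2 against 2 libraries allow. With each isoacceptor family counted once, by its most counted gene, tRNA shares were 30.9% and 30.3% in LRNP and 1.25% and 1.24% in PS.

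**Figure D1:**
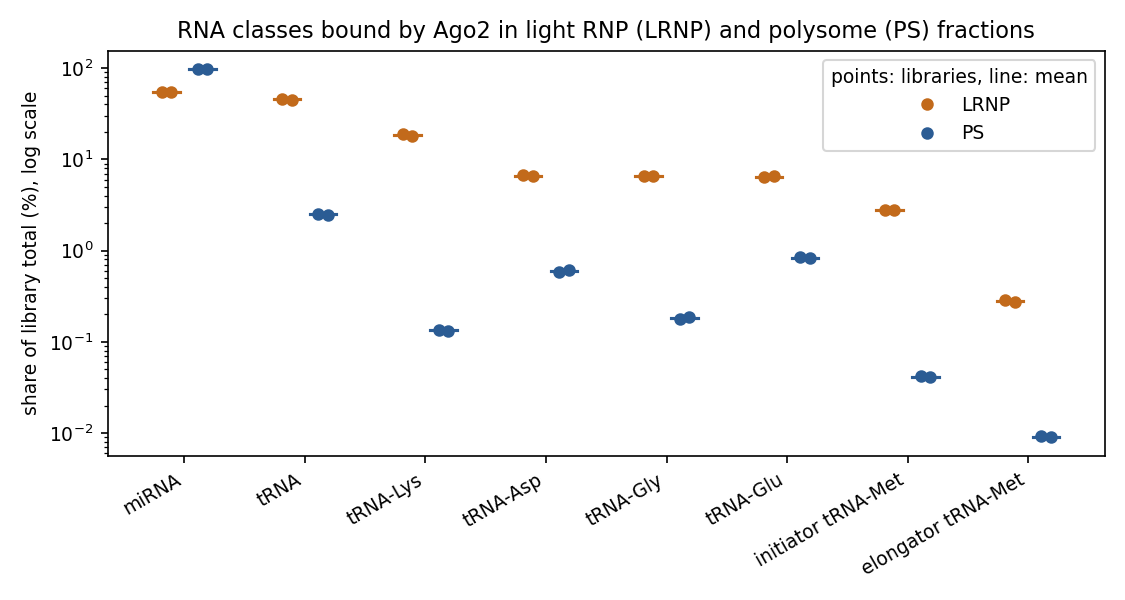
Share of each library's counted reads (percent, log scale) for miRNAs, all tRNAs and 6 groups of tRNAs in LRNP and PS. Points are the 2 libraries of a fraction and lines their mean; tRNA lay at 45.4% in LRNP and 2.50% in PS, and initiator tRNA-Met at 2.78% and 0.0414%.

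At the level of single features, most tRNA genes were higher in LRNP and most tested miRNAs were higher in PS. In edgeR's quasi-likelihood test, 1505 of 1578 tested features differed, 1027 higher in PS and 478 higher in LRNP. Of 268 tRNA genes, 257 were higher in LRNP, 8 were higher in PS and 3 did not pass. Of 1310 miRNAs, 1019 were higher in PS, 221 were higher in LRNP and 70 did not pass. In all 1505, both libraries of one fraction lay above both of the other, so the direction was necessarily the same with each antibody. This is no further support, because a test on the same libraries had selected these features. Of the 1019 miRNAs higher in PS, 820 had at most 10 reads in either LRNP library, and a minimum of 50 counts in 2 libraries left 402.

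Because the fractions differ so much in composition, the scaling sets where no change lies. The median log2 fold change over all tested features was 3.37 with TMM, and 2.58 with the 446 features at 0 in LRNP set to their lower bound. Other scalings moved the median by 0.64 (library totals), 0.95 (RLE) and 1.37 (upper quartile), and changes are given relative to TMM. Under these scalings 249, 246 and 240 tRNA genes were higher in LRNP.

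**Figure D2:**
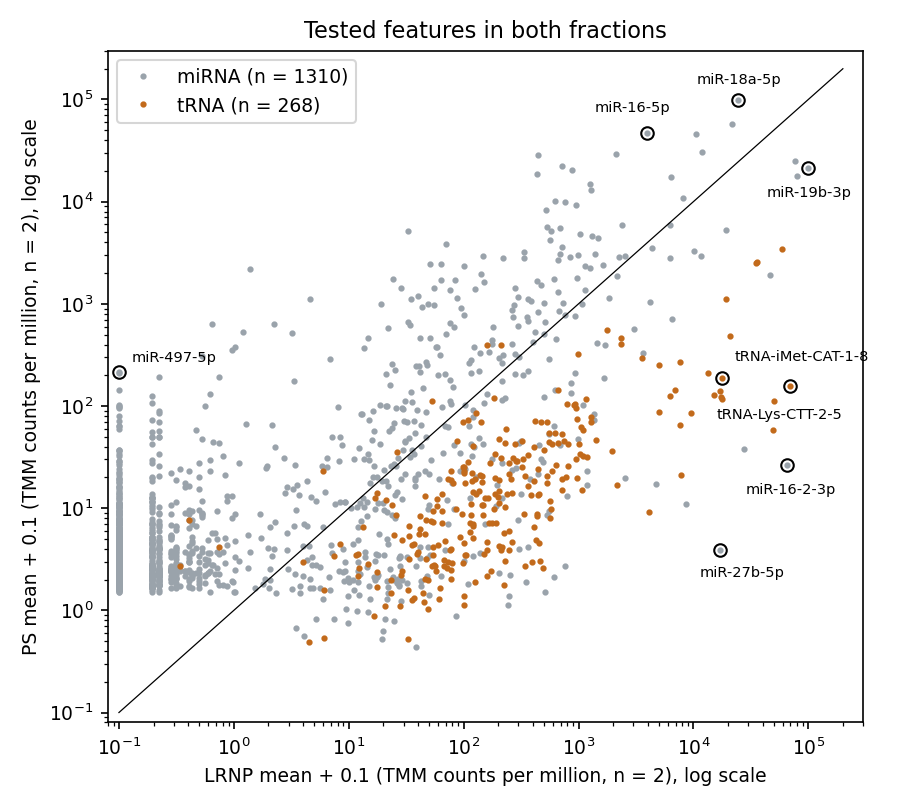
Mean level of each tested feature in LRNP (horizontal) and PS (vertical), in TMM-scaled CPM with 0.1 added, on log scales, with n = 2 libraries per fraction. The line marks equal levels; most of the 268 tRNA genes lie below it, and miR-16-5p and miR-16-2-3p lie on opposite sides of it.

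Both initiator tRNA-Met genes were among the most abundant tRNAs in LRNP, the 9th and the 12th of 268, and were 93.95-fold and 122.4-fold higher there than in PS. tRNA-iMet-CAT-1-8, on chromosome 17 from 82494721 to 82494792, had 17820 ± 544 CPM (SD, n = 2) in LRNP and 190 ± 20.0 CPM (SD, n = 2) in PS, with a log2 fold change of -6.55 (SE 0.17, edgeR adjusted p = 1.6e-252). tRNA-iMet-CAT-2-1 had 17210 ± 526 CPM in LRNP and 141 ± 6.53 CPM in PS, with a log2 fold change of -6.94 (SE 0.18, edgeR adjusted p = 7.2e-269). These near-identical genes share reads, so their levels are uncertain as those of single genes. By size of decrease they were the 20th and the 14th of 268 tRNA genes. Of the 7 elongator tRNA-Met genes, 6 were higher in LRNP and 1 in PS, over all features and adjusted over the list alone. tRNA-Met-CAT-4-3, on chromosome 6 from 26766234 to 26766306, had the highest level and a log2 fold change of -7.00 (SE 0.18). tRNA-Met-CAT-3-2 (-4.94), tRNA-Met-CAT-1-1 (-4.84), tRNA-Met-CAT-2-1 (-5.78), tRNA-Met-CAT-5-2 (-3.81) and tRNA-Met-CAT-6-1 (-3.70) were also lower in PS. In a fit of tRNA genes alone, 4 elongator genes were higher in LRNP, 1 was higher in PS and 2 did not pass, tRNA-Met-CAT-5-2 (-0.04) and tRNA-Met-CAT-6-1 (0.08). The exception was tRNA-Met-CAT-7-1, with 3 and 3 reads in LRNP and 28 and 35 in PS (log2 fold change 2.66, SE 0.58). By camera the elongator list was lower in PS (adjusted p = 0.0033), a call lost at adjusted p = 0.66 with an estimated correlation. Most features it was compared with were miRNAs (1310 of the 1578 tested features). The call therefore does not set elongator genes apart from other tRNAs.

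With the counts of each isoacceptor family summed, 48 of 49 families were higher in LRNP and 1 was higher in PS in edgeR's test. The lysine families had the largest decreases, with log2 fold changes of -9.14 (SE 0.15) for tRNA-Lys-TTT and -8.40 (SE 0.15) for tRNA-Lys-CTT, followed by tRNA-Gly-CCC (-8.24) and tRNA-Arg-ACG (-7.78). The initiator family stood at the 5th place with -7.66 (SE 0.15) and the elongator tRNA-Met family at the 7th with -6.54 (SE 0.16), against a median of -4.60 over the families. The initiator family differed from that median by -3.07. This fit has its own scaling, under which the tested miRNAs lay lower by a median log2 change of -0.89 than in the fit of single genes. Family values are therefore not comparable with those of single genes, such as -6.55 and -6.94 for the initiator genes. The 8 families most abundant in LRNP held 88.1% of tRNA reads in LRNP and 63.8% in PS. Within the tRNA reads of PS, tRNA-Glu-CTC took 25.6% and tRNA-Asp-GTC 23.9%, whereas in LRNP tRNA-Lys-CTT took 21.4% and tRNA-Lys-TTT 19.2%.

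The smallest decreases were those of tRNA-Ser-CGA (-2.46), tRNA-His-GTG (-2.61) and tRNA-Val-TAC (-0.49, SE 0.13, adjusted p = 0.0002). The direction of the family tRNA-Val-TAC depended on the scaling, with log2 fold changes of 1.11 with library totals and 0.31 with upper-quartile scaling, and with RLE it did not pass (-0.06, adjusted p = 0.56). tRNA-Tyr-ATA, higher in PS (3.60, SE 0.66), had few reads, at 0.431 CPM in LRNP and 5.51 CPM in PS. By camera all nuclear tRNAs were lower in PS (adjusted p = 1.1e-75), with adjusted p = 0.079 with an estimated correlation.

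**Figure D3:**
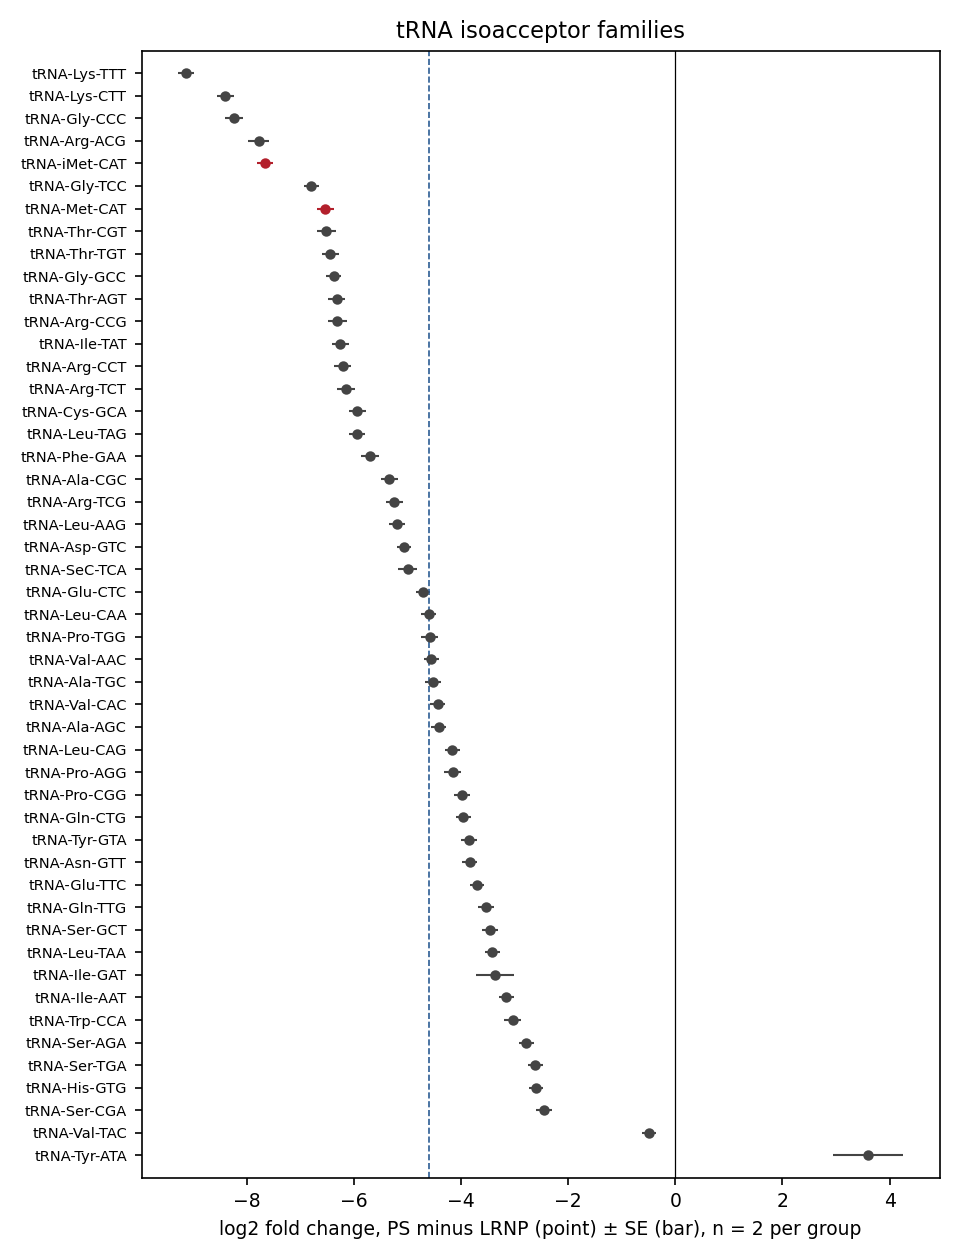
Log2 fold change (PS minus LRNP) of the 49 tRNA isoacceptor families, as points with bars of 1 SE, n = 2 libraries per fraction; the dashed line is the family median of -4.60 and the tRNA-Met families are red. The initiator family, at -7.66, is the 5th from the top, and tRNA-Val-TAC lies at -0.49, though above 0 with library totals or upper-quartile scaling.

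Of the most abundant single tRNA genes, tRNA-Lys-CTT-2-5, on chromosome 16 from 3175691 to 3175763, had 69030 ± 3416 CPM (SD, n = 2) in LRNP and 159 ± 6.29 CPM in PS (log2 fold change -8.77, SE 0.20). tRNA-Lys-TTT-5-1, on chromosome 11 from 59556429 to 59556501, fell from 49110 to 58.6 CPM (-9.71, SE 0.20), and tRNA-Lys-TTT-3-5 changed by -8.81. tRNA-Gly-GCC-5-1 (-8.82) and tRNA-Gly-CCC-1-2 (-8.50) were also among the 12 largest decreases. tRNA-Asp-GTC-2-11 fell less, from 59640 to 3407 CPM (-4.13, SE 0.16).

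The miRNA families were compared by the arm of the hairpin they come from. let-7 and miR-15/16 split between 5p and 3p arms, whereas miR-17~92 did not when its arms were pooled in this way. The let-7 group, a family that represses growth-promoting mRNAs, held 0.309% ± 0.00159 (SD, n = 2) of LRNP reads and 4.89% ± 0.217 (SD, n = 2) of PS reads, 15.8-fold more in PS, and 8.84-fold more as a share of miRNA reads alone. All 9 tested let-7 5p arms were higher in PS, whereas of 9 tested 3p arms 6 were higher in LRNP, 2 were higher in PS and 1 did not pass. Together 11 of 18 members were higher in PS and 6 in LRNP, with the same counts adjusted over the list alone. let-7a-5p rose from 875 ± 17.3 to 20250 ± 2998 CPM (SD, n = 2; log2 fold change 4.53, SE 0.16, edgeR adjusted p = 4.2e-158), let-7f-5p by 3.28 and let-7g-5p by 2.16.

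The miR-15/16 family, which targets cell cycle genes, split by arm in the same way. All 7 tested 5p arms were higher in PS, and of 8 tested 3p arms 6 were higher in LRNP and 2 in PS. Over the list 9 of 15 members were higher in PS and 6 in LRNP, also adjusted over the list alone. miR-16-5p, made from hairpins in DLEU2 and in an intron of SMC4, rose from 3915 ± 105.8 to 47440 ± 2810 CPM (SD, n = 2; log2 fold change 3.60, SE 0.15, edgeR adjusted p = 4.2e-111). From the opposite arm of the SMC4 hairpin, on chromosome 3 from 160404745 to 160404825, miR-16-2-3p fell from 65030 ± 375 to 26.4 ± 4.42 CPM (SD, n = 2; -11.26, SE 0.22). miR-16-1-3p, from the DLEU2 hairpin on chromosome 13, fell from 27810 to 37.8 CPM (-9.52, SE 0.20). These splits by arm had the same direction in the median of each arm under RLE, library-total and upper-quartile scaling.

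The miR-17~92 cluster and its paralogs, a growth-promoting group, held 25.8% ± 0.120 (SD, n = 2) of LRNP reads and 46.4% ± 0.240 (SD, n = 2) of PS reads. This difference goes with the tRNA reads in LRNP, since the group held 47.3% ± 0.645 (SD, n = 2) of the miRNA reads in LRNP and 47.6% ± 0.230 (SD, n = 2) in PS. Of 24 tested members 15 were higher in PS, 8 were higher in LRNP and 1 did not pass, with the same counts adjusted over the list alone. Both arms went both ways, with 9 of 13 5p arms higher in PS and 4 in LRNP, and 6 of 11 3p arms higher in PS and 4 in LRNP. Their medians were 1.38 and 1.46, and 0.24 and -0.47 in a fit of miRNAs alone. Pooled arms can hide a split within hairpins. The arm usually loaded by Ago2 is 3p for miR-19a, miR-19b, miR-25 and miR-92a and 5p for miR-17, miR-18a, miR-20a and miR-93. In miR-20a, miR-25, miR-92a and miR-93 that arm was higher in PS and the opposite arm in LRNP. The group's other hairpins with both arms compared did not split in this way. miR-18a-5p rose by 2.00 (SE 0.15) to 98110 ± 9889 CPM (SD, n = 2), miR-17-5p by 2.14 (SE 0.14) and miR-20a-5p by 1.38 (SE 0.14) on the log2 scale. miR-19b-3p fell from 99510 ± 4586 to 21410 ± 3007 CPM (SD, n = 2; -2.22, SE 0.15) and miR-19a-3p changed by -2.15 (SE 0.15). The hairpins of these 5 miRNAs lie within 1 host transcript, MIR17HG, on chromosome 13, where miR-17 starts at 91350605 and miR-19b-1 ends at 91351278; miR-19b-3p also has a hairpin on chromosome X. miR-92a-1-5p, from the same transcript, changed by -9.62 (SE 0.21).

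**Figure D4:**
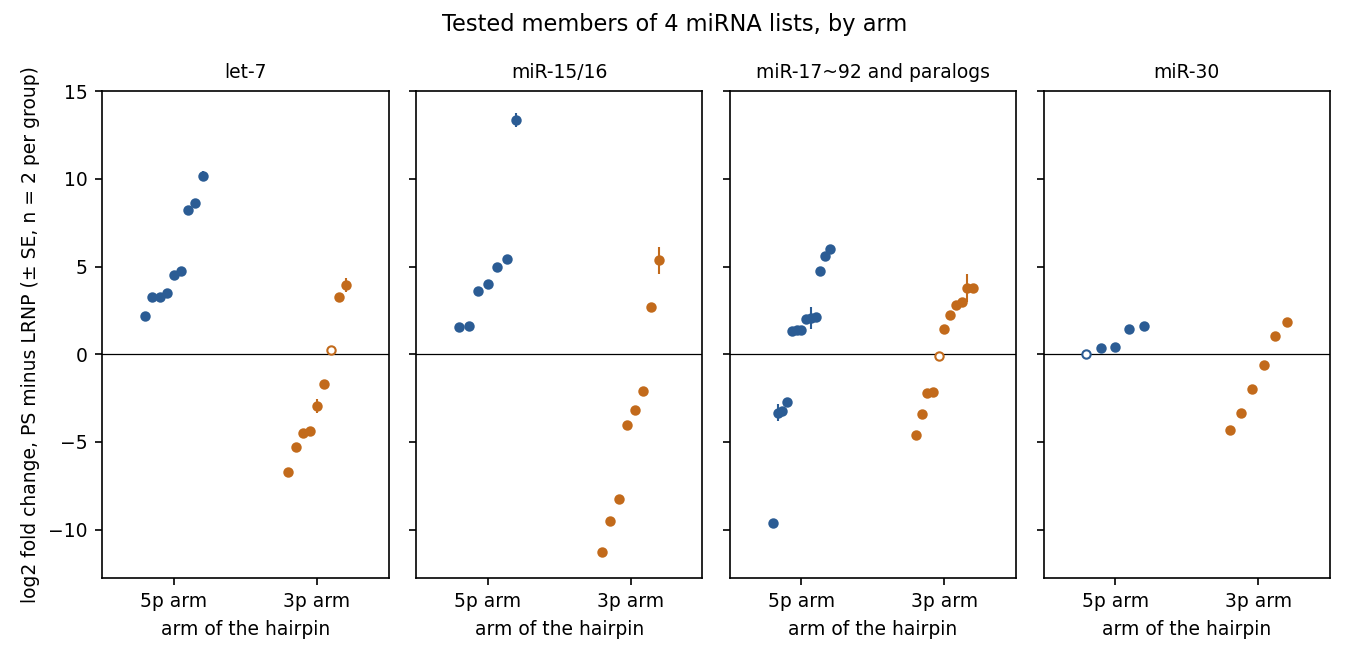
Log2 fold change (PS minus LRNP, with bars of 1 SE, n = 2 libraries per fraction) of tested members of 4 miRNA lists, separated into 5p and 3p arms; open points did not pass the test. All 9 let-7 and all 7 miR-15/16 5p arms lie above 0, and 6 of the 3p arms of each list lie below it and passed.

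Of 14 tested members of the miR-10 family (with miR-99, miR-100 and miR-125), 11 were higher in PS and 3 in LRNP, also adjusted over the list alone. These were all 7 5p arms and 4 of 7 3p arms in PS, and 3 3p arms in LRNP; the 3p median of 0.53 was -1.24 with at least 50 counts in 2 libraries and -2.03 in a fit of miRNAs alone. In that fit 7 members were higher in PS, 5 were higher in LRNP and 1 did not pass, with a median of 0.73 against 2.30. miR-125a-5p rose by 3.44 (SE 0.15) and miR-10b-5p by 1.04 (SE 0.14; -0.10, adjusted p = 0.24, in a fit of miRNAs alone) on the log2 scale, whereas the change of miR-10a-5p was 0.44 (SE 0.14, edgeR adjusted p = 0.0015; -0.70 in a fit of miRNAs alone) and did not pass without a filter (0.00, adjusted p = 0.99), without LRNP replicate 1 (0.08) or without LRNP replicate 2 (0.29). Of 11 tested members of the miR-30 family, 6 were higher in PS, 4 were higher in LRNP and 1 did not pass, also adjusted over the list alone. With RLE or upper-quartile scaling 8 were higher in PS and 3 in LRNP, and in a fit of miRNAs alone 3 were higher in PS and 7 in LRNP. Its median was 0.34, and -0.79 in that fit, and its mean was -0.329. By arm, 4 of 5 5p arms were higher in PS, and of 6 3p arms 2 were higher in PS and 4 in LRNP. The direction of the 5p arms depended on the scaling. In the fit of miRNAs alone 2 of them were higher in PS and 3 in LRNP, with a median of -0.69 against 0.44. miR-30c-5p rose by 1.45 (SE 0.14) and miR-30e-3p by 1.81 (SE 0.14); miR-30b-5p had 0.34 (SE 0.13), which became -0.07 without LRNP replicate 1 and did not pass without LRNP replicate 2 (0.25).

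The group of miR-302 and miR-371, typical of stem cells, was low in both fractions, at 0.00235% of LRNP and 0.0168% of PS reads (0.00430% and 0.01725% of miRNA reads). Of 7 tested members 6 were higher in PS and 1 in LRNP, also adjusted over the list alone. miR-302a-3p had 0 reads in LRNP and 442 in PS, at least 91.0-fold higher in PS against a floor of 3 counts over the group. miR-367-3p had 1 read in LRNP and 856 in PS, a ratio of 528 with a 95% counting interval from 94.6 to 20900. miR-302b-3p was lower in PS with TMM (-0.54, SE 0.20, edgeR adjusted p = 0.006), but its log2 fold change was 0.42 with RLE, 0.10 with library totals and 0.84 with upper-quartile scaling, and it did not pass without PS replicate 1 (-0.31, adjusted p = 0.079).

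The camera test placed miRNAs as a class above the other features in PS (adjusted p = 1.1e-75), with adjusted p = 0.079 with an estimated correlation. All of those other features are tRNA genes, so this is the nuclear tRNA contrast above seen from the other side. Camera made no call for the 5 family lists, the miR-302 group or the list of tissue-restricted miRNAs, with adjusted p from 0.47 to 0.97. Its direction was down relative to the other features for let-7, miR-17~92 and miR-15/16, whose medians (3.28, 1.42 and 1.61) and means (1.69, 0.515 and 0.288) were above 0, and for miR-30. By fry's test of each list's own direction, 7 of 10 lists passed, and let-7 (adjusted p = 0.03) and miR-10 (adjusted p = 0.031) were up. For miR-17~92, miR-15/16 and miR-30 fry gave adjusted p = 0.21, with a downward sign for miR-15/16. The median of all tested miRNAs was 4.24, and 2.93 with the 446 at 0 in LRNP set to their lower bound.

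The largest changes toward LRNP included miR-27b-5p, from a hairpin in an intron of C9orf3 on chromosome 9, which fell from 17050 ± 182 to 3.77 ± 0.829 CPM (SD, n = 2; -12.15, SE 0.24), miR-141-5p (-8.47), miR-503-3p (-8.23) and miR-4488 (-8.17), together with the miR-16 3p arms, miR-92a-1-5p and the tRNA genes above. miR-4488 had LRNP counts of 2284 and 5154, and its call was lost without PS replicate 1 (-8.23, adjusted p = 0.11) or PS replicate 2 (-8.11, adjusted p = 0.12), with log2 fold changes of about the same size. The 12 features with the largest fitted changes toward PS all had 0 reads in both LRNP libraries, so only lower bounds are given for them and their rank among all features is not established. miR-497-5p had 1265 and 2051 reads in PS, at least 682-fold higher, and miR-4288 had 1340 and 1884 reads, at least 664-fold higher. miR-551a was at least 452-fold higher and miR-500a-3p at least 328-fold. For miR-6720-3p, miR-491-5p, miR-512-3p, miR-3909, miR-5682, miR-3943, miR-4286 and miR-3157-5p the lower bounds ran from 322-fold to 188-fold. Among abundant miRNAs, miR-221-3p, from MIR222HG on chromosome X, fell from 76860 ± 268 to 24790 ± 1595 CPM (SD, n = 2; -1.63, SE 0.14).

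Tissue-restricted miRNAs, listed as markers of RNA from outside the line, held 0.112% ± 0.00228 (SD, n = 2) of LRNP reads and 0.196% ± 0.000907 (SD, n = 2) of PS reads, but 0.205% and 0.201% of the miRNA reads. Of 13 tested members 8 were higher in PS, 3 were higher in LRNP and 2 did not pass, also adjusted over the list alone. The list's median log2 fold change was 6.52, and 2.53 with the 7 members at 0 in LRNP set to their lower bound. With at least 50 counts in 2 libraries it was 1.16 (of 8 tested, 5 higher in PS and 3 in LRNP), and in a fit of miRNAs alone it was 0.58 (of 11 tested, 6 higher in PS and 5 in LRNP). Most of its reads came from miR-9-5p, a neuronal miRNA, with 1136 ± 7.14 CPM in LRNP and 1358 ± 141.5 CPM in PS (SD, n = 2; 0.26, SE 0.13, edgeR adjusted p = 0.056). That value was 1.23 with RLE and 0.92 with library totals, where it passed, and -0.14 without LRNP replicate 1. The blood miRNAs miR-486-5p (-2.66, SE 0.15) and miR-142-3p (1.72, SE 0.15) changed in opposite directions. How many of these miRNAs HEK293T cells express was not tested.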

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

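The fit within each class, the counts with 1 gene for each tRNA family and the shares of miRNA reads only were chosen after the data were seen; the other settings were fixed before. The number of differing features was 1505, and 1481 to 1519 with other scalings, DESeq2 or voom. Without a filter it was 2342 (1847 higher in PS, of them 1841 miRNAs), and with at least 50 counts in 2 libraries it was 799 (413 higher in PS, of them 402 miRNAs, with 145 miRNAs higher in LRNP), since a filter sets how many features are tested. Not all calls kept their direction. Opposite to the main fit were 18 calls with RLE, 7 with library totals, 39 with upper-quartile scaling and 15 with DESeq2. There were also 21 with at least 50 counts in 2 libraries, 119 in the fit within each class and 0 with voom. The miRNAs higher in LRNP numbered 221, and 166 with RLE, 177 with library totals, 149 with upper-quartile scaling and 154 with DESeq2. In the fit of miRNAs alone they numbered 299. Fitted apart from miRNAs, 124 tRNA genes were higher in LRNP and 104 in PS, since changes are then relative to the tRNAs. The families higher in LRNP numbered 47 or 48 in every setting run for them, but families were not fitted apart from miRNAs. Camera called 3 lists, of which miRNAs and nuclear tRNAs are 1 contrast, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). The fry test, which asks about each list's own direction, called 7. The miR-30 list gained a camera call without a filter (adjusted p = 0.0279). The tRNA share differed by 42.95 percentage points, 46.5 without the most abundant feature of each library and 29.39 with each family counted once. With each library left out in turn, differing features ranged from 1371 to 1869, features higher in PS from 899 to 1364 and the difference in tRNA share from 42.6 to 43.29; the lone library is then assumed to vary like the other group.

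With the replicate block, a paired fit on the antibody, 1489 features differed, 1484 of them shared with the 1505 and in the same direction. The block changed no call of a named feature, family or list.

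Of 56 named features 48 kept direction and call in every setting. Of 49 families 48 did so in the settings run for families, which did not include the fit within each class. The cause of the exceptions was not tested. The family tRNA-Val-TAC had 1.11 with library totals, 0.31 with upper-quartile scaling and 0.13 with the strict filter, and did not pass with RLE (-0.06), DESeq2 (-0.06) or its most counted gene (-0.01). miR-302b-3p had 0.42 with RLE, 0.10 with library totals, 0.84 with upper-quartile scaling, 0.53 with the strict filter and 0.41 with DESeq2. Without a filter, miR-30b-5p had -0.10 and miR-9-5p -0.18, and miR-10a-5p did not pass (0.00). Fitted within their class, miR-10a-5p had -0.70, miR-10b-5p -0.10, miR-30b-5p -0.79, miR-9-5p -0.88 and tRNA-Met-CAT-6-1 0.08, and tRNA-Met-CAT-5-2 did not pass (-0.04). With each library left out in turn, miR-30b-5p ranged from -0.07 to 0.36 and miR-9-5p from -0.14 to 0.31. As shares of miRNA reads only, the PS minus LRNP difference changed from 4.747 to -1.788 percentage points for miR-15/16 and from 0.08455 to -0.003451 for the tissue-restricted list, since the tRNA reads of LRNP are then left out. Fits without ribosomal or mitochondrial features were not run, because no such features were in the table used.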

Other observations

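All tests of arm role, arm position, abundance and library depth were chosen after the fold changes had been seen; the test of host mRNA fragments was chosen before its result was seen. The list of guide arms was also written after some of their fold changes had been seen, and features named only in this part were chosen after their values were seen.

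Opposite arms of single hairpins often went to opposite fractions, in members of the lists above and in other miRNAs. miR-193b-3p rose from 3.13 to 523.5 CPM and miR-193b-5p fell from 243 to 1.04 CPM. miR-92a-3p rose from 2120 to 28960 CPM, against the decrease of miR-92a-1-5p. For 92 well-known miRNAs the arm usually loaded as guide was written down from textbook knowledge, and 83 of them had both arms tested. Of the 83 guide arms 69 were higher in PS, 10 were higher in LRNP and 4 did not pass. Of 96 passenger arms 60 were higher in LRNP, 31 were higher in PS and 5 did not pass. These counts depend on the scaling. In a fit of miRNAs alone, over 80 hairpins, 51 guides were higher in PS and 66 passengers in LRNP. With RLE the counts were 74 and 57, and with upper-quartile scaling 74 and 55. Among all 1310 tested miRNAs 1019 were higher in PS, so the guide count alone does not set guides apart. The median log2 fold change was 1.80 for guides and -2.40 for passengers, against 4.24 for all tested miRNAs. By edgeR's test, the guide was higher in PS and the passenger in LRNP in 39 hairpins, and 0 had the reverse, also 0 at an unadjusted p under 0.05 and 0 by limma voom, but 1 by DESeq2.

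A candidate explanation is that passenger arms meet Ago2 in light complexes, for example as duplexes during loading, and guides go on to polysomes. The median guide-minus-passenger difference in log2 fold change was 3.66 over 83 hairpins (interquartile range 0.58 to 6.85, above 0 in 64; sign-flip permutation p = 1e-05, the smallest 100000 draws can give), and 3.66 with arms at 0 in LRNP set to their bound. This median measures the pattern itself and does not support that explanation, which stays open because no test here separates it from others. The sign-flip p measures the spread over hairpins and not between samples. The hairpins are not independent, since all were measured in the same libraries and some are close relatives. Arm position as the cause is argued against, since the median was 3.66 in 51 hairpins with a 5p guide and 3.59 in 32 with a 3p guide, and low abundance too, since the passenger median of -2.40 lay below the central 95% (1.07 to 2.95) of the medians of 10000 abundance-matched lists of other miRNAs. Precursor fragments and differences in ligation were not tested, and hairpins such as miR-19b (-1.65) and miR-17 (-0.11) went the other way, as did miR-21 and miR-186, whose passenger arms had 0 reads in LRNP.

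Of the 2654 miRNA features, 1847 had at most 1 read in each LRNP library, and 1806 of these had reads in both PS libraries, with a median mean count of 10. The 1847 include 665 of the 1019 miRNAs called higher in PS. The choice of these miRNAs caps their LRNP reads, so the depth of counted reads was judged on miRNAs chosen in 1 LRNP library and counted in the other. A difference in counted reads is argued against, as mean totals over the counted features differed by a factor of 1.036. Totals of miRNA reads were 2855157 and 3652947 in LRNP and 4963348 and 7078849 in PS. The mean PS reads of such miRNAs were 66.3 times those of LRNP replicate 2 (833 reads). Against LRNP replicate 1 (355 reads) they were 143 times as many. The depth of all sequenced reads is not known here, so its part stays open. Whether fragments of polysomal mRNAs were counted as miRNAs stays open. The median PS count of hairpins in coding exons was 1.77 times that of hairpins between genes (11.5 over 231 miRNAs against 6.5 over 340). This lay below the factor of 2 set beforehand. A two-sided permutation test over miRNAs, which are not independent, gave p = 1e-05, the smallest 100000 draws can give. Hairpins in introns had a median of 11 over 767 miRNAs, so the ratio does not set exons apart from introns. Reads carried over between PS libraries and index errors were not tested.

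miR-4787-3p had 6 and 6 reads in the LRNP libraries and 15435 and 17852 in the PS libraries. tRNA-Val-TAC-1-2 and tRNA-Val-TAC-2-1 were among 8 tRNA genes higher in PS, with log2 fold changes of 0.91 (SE 0.13) and 1.30 (SE 0.13).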
